A study of Rattus norvegicus with 6 samples.

How the data were processed

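Ileum RNA of 6 Zucker fa/fa rats was measured on Affymetrix whole-transcript arrays for the rat, 1 array per rat, and the labels assign 3 rats to sham surgery and 3 to duodenum-jejunum bypass (DJB). The labels number the rats of each group from 1 to 3 as biological replicates, and each array is named here by its group and that number.

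The deposited table of the whole series holds log2 expression values, 29214 rows by 6 arrays, and each column was matched to its sample by name. RMA is the only method named, per the submitters' processing notes, with no version, and RMA corrects background, quantile normalises between arrays and summarises the probes of a row on the log2 scale. The values were used as deposited, with no further background correction or normalisation. Quantile normalisation gives arrays nearly the same distribution, so that a change shared by most genes cannot be seen, and summarised values of dim probes understate fold changes. The array medians over all rows were 6.09, 6.11 and 6.09 for sham 1 to 3 and 6.19, 6.08 and 6.10 for DJB 1 to 3. The precision is limited by the number of arrays. Scan dates, scanner intensities and processing batches were not analysed here, and the labels give no batch.

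Gene names came from a table that pairs the rows with the annotation of the array platform. Of the rows, 15310 carried 1 gene symbol, 323 carried several and 13581 carried none there. Looked up in a RefSeq gene table of the assembly GRCr8, used for names only, the symbols of 15279 rows were found, those of 31 were not found and were kept, and 0 were replaced. No coordinates are given, because the genome build behind the rows is not given in the sources used here. Rows with several symbols or none were left out of the main test. Where several rows stood for a gene (527 genes), the row with the highest mean over all 6 arrays was taken, which left 14506 genes. Of the genes called, 3 had several rows, and in 0 of them did the rows move in opposite directions.

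Differences between DJB and sham were tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with no covariate and no filter on dim rows, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All changes are DJB minus sham, and their SE is that of the moderated fit. As a secondary count, genes at an unadjusted p under 0.01 and at least 1.5-fold were given beside the number chance gives. Exact permutation tests of 3 against 3 arrays cannot give a two-sided p under 0.1. Principal components were computed over the genes tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

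The tests, their alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The 35 lists came from general knowledge of the ileum, of bypass surgery, of the cell types of the gut wall and of signs of tissue handling. They cover ileal bile acid handling and FXR targets; cholesterol synthesis and uptake; sterol transport and LXR targets; fat absorption, fatty acid oxidation and synthesis, gluconeogenesis, brush border digestion and transport, and proximal small intestine markers. They also cover enteroendocrine, goblet, Paneth, tuft, crypt stem and dividing cells, T and NK cells, B and plasma cells, macrophages with dendritic cells and neutrophils, mast cells with eosinophils, inflammatory cytokines, interferon response, MHC class II, smooth muscle, fibroblasts, neurons and glia, endothelium, adipocytes, exocrine pancreas, red blood cells, xenobiotic metabolism, unfolded protein response, circadian clock, immediate early genes, glycolysis and oxidative phosphorylation. Most of these genes are also expressed by normal ileum, and 1 gene is in more than 1 list. Lists with at least 4 measured members were tested with camera in limma at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists, and with the correlation estimated per list and with fry as alternatives. Members were also adjusted over the list alone. A list's mean and SE come from the mean of its genes on each array.

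The genes named were the 10 with the largest rise and the 10 with the largest fall among genes past the adjusted threshold whose groups did not overlap, leaving out names that are only an accession or a predicted-gene number. Added to these were the bile acid list members past a list-alone threshold of 0.05 with Fgf15, Nr1h4, Nr0b2, Slc10a2, Fabp6, Slc51a and Slc51b in any case. Up to 4 members of lowest p were taken from every other list that was called or held a called gene, and up to 2 from each remaining list. In addition, Nfkbia, Nupr1, Slc11a2, Srebf2, Si, Anpep, Vil1, Hbb and all genes first named in the closing section were chosen after their values were seen.

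The alternatives were the replicate number as a block, quantile normalisation repeated, each array centred on its median, dim rows left out (mean under the median of all rows), eBayes with an intensity trend and a robust prior, array weights, the mean of all rows of a gene, all rows tested singly, a plain two-sample test with pooled variance, and each array left out in turn. With each gene drawn independently, the fit was tested on simulated data with the moderated variances of the 14506 genes and 200 genes changed. It recovered 66% of the genes changed by 0.5 on the log2 scale and 100% of those changed by 1, by 1.5 and by 2, with 10 false calls among 193 (5.18%). In simulated lists the planted list was called, with 1 of the others. Genes of real lists can be correlated, with an estimate of 0.85 for smooth muscle. The simulation leaves that out and does not show how calls behave under it. Moderated variances also differ less between genes than the unmoderated ones do, so the percentages recovered may be too high for real genes.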

Results

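The data are gene expression profiles of the ileum, the last part of the small intestine, in 6 Zucker fa/fa rats, an obese strain with a defective leptin receptor. In 3 rats a duodenum-jejunum bypass (DJB) routed food past the duodenum and the upper jejunum. The other 3 rats had a sham operation, after which food kept its normal course through the gut. The rats were 20 weeks old, and tissue was taken 14 days after surgery. RNA of each rat was hybridised to 1 Affymetrix whole-transcript array, and the values are log2 expression levels after RMA normalisation. The 6 arrays had median levels between 6.08 and 6.19, and the number of arrays limits the precision of every comparison below. The design holds a single comparison, DJB against sham, and the title of the series ties it to the gut hormone FGF19. Changes are given as DJB minus sham on the log2 scale with their standard error (SE), from 3 arrays per group, and a gene rose or fell where its limma adjusted p over all genes tested was under 0.05.

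After the bypass, the ileum carried more transcript of the enzymes that make cholesterol. Squalene epoxidase, Sqle, rose 3.33-fold, and 13 of the 19 cholesterol genes measured rose. Slc10a2, the ileal transporter that takes up bile acids, rose 3.32-fold, and Nr1h4, which encodes the bile acid receptor FXR, rose 1.97-fold. The sterol exporters Abcg5 and Abcg8 fell 4.0-fold and 3.29-fold, and Enpp7, the intestinal enzyme that digests sphingomyelin, fell 12.6-fold. The antimicrobial lectins Reg3b and Reg3g rose 3.97-fold and 3.20-fold.

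In all, 112 of the 14506 genes tested passed the adjusted threshold, 57 higher and 55 lower after DJB, and in each of the 112 the 3 DJB values lay wholly above or below the 3 sham values. Among all genes tested, 21.1% had groups that did not overlap, where chance gives 10% for 3 against 3 arrays. A change of at least 2-fold was seen for 22 of the genes that rose and 30 of those that fell. At an unadjusted p under 0.01, 735 genes were found where chance gives 145, and 200 of them (88 higher, 112 lower) differed at least 1.5-fold. The 6 arrays correlated with one another at 0.990 to 0.993 within a group and at 0.987 to 0.990 between groups. These correlations run across all 29214 rows, which are not independent replicates. The leading principal component held 38.0% of the variance and separated the groups, while the next, with 21.7%, spread the DJB arrays from 19.1 for DJB 1 to -16.1 for DJB 3. The number of genes called was 61 without sham 1, 37 without sham 2, 33 without sham 3, 43 without DJB 2 and 60 without DJB 3, and 24 genes (17 higher, 7 lower) were called whichever array was left out.

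The falls were led by Enpp7, which went from 9.93 ± 0.16 (SD, n = 3) in sham to 6.28 ± 0.39 (SD, n = 3) after DJB, a change of -3.66 ± 0.18 (SE). Slc5a4 and Slc5a4b, members of the sodium-glucose cotransporter family, changed by -3.56 ± 0.50 and -1.81 ± 0.16. Enpp3, an ectoenzyme that splits nucleotides, changed by -2.97 ± 0.15, and Asah2, the neutral ceramidase that acts after sphingomyelinase, by -2.61 ± 0.46. Fam151a fell by 2.79 ± 0.41 and Ugt2a3, a glucuronosyltransferase, fell by 2.58 ± 0.23. The proton-coupled folate transporter Slc46a1 fell by 2.38 ± 0.29, Abcg5 fell by 2.0 ± 0.32, and the lipid-binding protein gene Sec14l2 fell by 1.73 ± 0.29. Among these 10, the calls of Enpp7, Enpp3, Ugt2a3 and Slc5a4b held whichever array was left out. The others ended when 1 array was removed: Slc5a4 without sham 2, sham 3 or DJB 2 (adjusted p up to 0.103), Slc46a1 without sham 3 or DJB 2 (up to 0.0576), Abcg5 without sham 2, sham 3, DJB 2 or DJB 3 (up to 0.142), and Fam151a, Asah2 and Sec14l2 without any of the sham arrays or DJB 3 (up to 0.107, 0.167 and 0.150).

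The rises were led by C3, the central complement component, which went from 5.45 ± 0.30 (SD, n = 3) to 7.51 ± 0.17 (SD, n = 3), a change of 2.06 ± 0.16 (SE). Reg3b rose by 1.99 ± 0.17 and Reg3g by 1.68 ± 0.14 from already high levels of 11.09 and 11.75 in sham. Sulfite oxidase, Suox, rose by 1.74 ± 0.22, and Slc5a8, a sodium-coupled transporter of short-chain fatty acids and lactate, by 1.53 ± 0.16. Epiregulin, Ereg, a ligand of the EGF receptor, rose by 1.34 ± 0.17. The other genes among the 10 largest rises were Slc10a2 and the cholesterol genes Sqle, Msmo1 and Idi1. The calls of Suox and Ereg ended without sham 2 (adjusted p = 0.0520) and without DJB 2 (adjusted p = 0.0610), respectively.

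**Figure D1:**
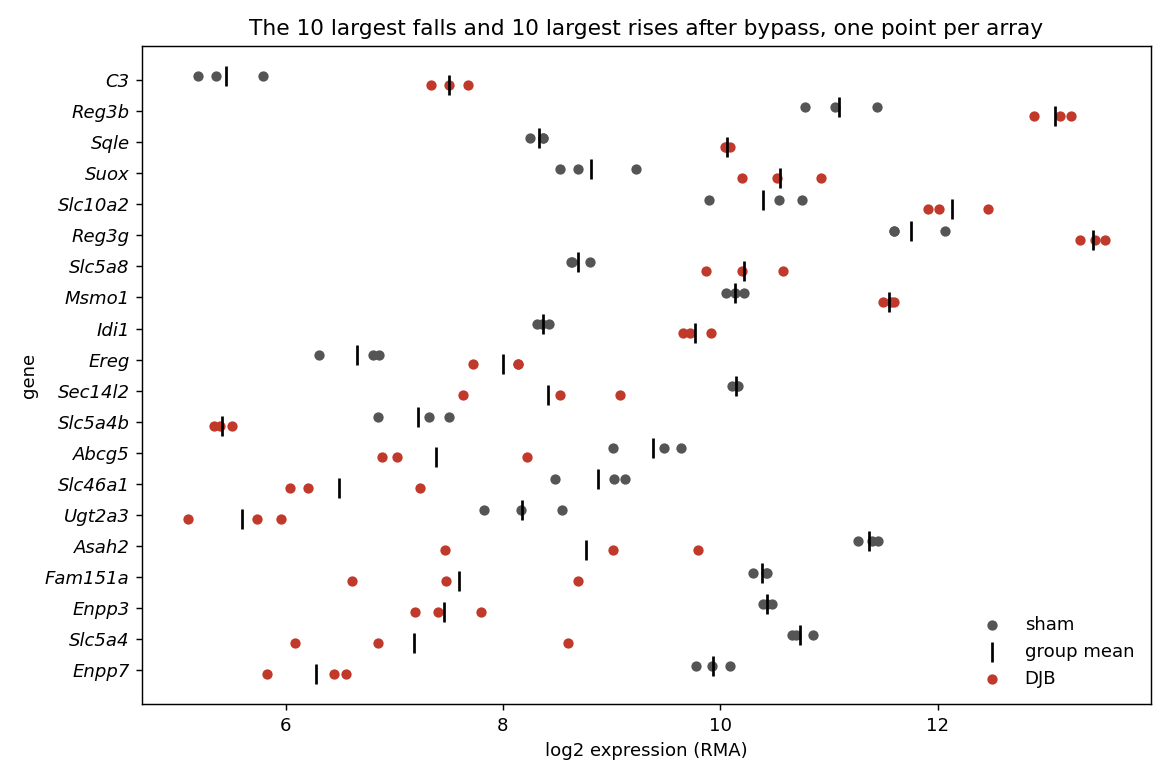
Log2 expression (RMA) of the 10 genes that fell most and the 10 that rose most after DJB, with 1 point per array (3 sham in grey, 3 DJB in red) and a black bar at each group mean. The sham and DJB points of each gene do not overlap. Among the 10 falls, the DJB points lie closest together for Slc5a4b, Enpp3 and Enpp7 (SD 0.08, 0.31 and 0.39). Those of Slc5a4, Fam151a and Asah2 spread widest.

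Bile acid genes of the ileum were measured for 13 members of the list fixed for them. Of these, 3 rose over all genes, and 7 rose and 1 fell when adjusted over the list alone. Slc10a2 changed by 1.73 ± 0.22 (adjusted p = 0.0106), Nr1h4 by 0.98 ± 0.15 (adjusted p = 0.0275) and Abcc3, an export pump of the basolateral membrane, by 0.61 ± 0.10 (adjusted p = 0.0289). Passing over the list alone were also Fabp6, the ileal bile acid binding protein, at 0.30 ± 0.10, Slc51a, a subunit of the basolateral bile acid exporter, at 0.37 ± 0.13, Slc27a5 at 0.48 ± 0.14 and the bile acid receptor gene Gpbar1 at 0.31 ± 0.11, while the apical pump gene Abcc2 was lower by that test at -1.13 ± 0.27. Fabp6 lay at 13.57 in sham and 13.88 after DJB, near the top of the scale (the highest value of any row was 13.85 on sham 1 and 14.04 on DJB 1), where a difference can be understated. Slc27a5 (4.41 in sham, 4.89 after DJB) and Gpbar1 (5.32 and 5.63) lay under 6.11, the median of all rows, so their rises rest on dim rows. Nr0b2, which encodes the FXR-induced repressor SHP, differed by 0.54 ± 0.58 and did not pass, and Slc51b was not analysed here. The Nr0b2 difference was 0.15 without DJB 1, 0.17 without DJB 2, 0.16 without sham 1, 0.87 without sham 3 and 1.29 without DJB 3. The list as a whole was called higher by camera (mean 0.37 ± 0.25, adjusted p = 0.00967), a call that was lost with an estimated correlation (adjusted p = 0.639) and without sham 1 (adjusted p = 0.0573). The call of Nr1h4 ended without any 1 of the sham arrays (adjusted p up to 0.113) and that of Abcc3 without any 1 of the 6 arrays (up to 0.113), and the list-alone count of 7 was 3 without sham 1 or DJB 2 and 4 without DJB 1.

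The gene for FGF19 is named Fgf19 in the rat annotation used here and is the rodent gene long known as Fgf15, the hormone that the ileum releases in response to bile acids. Its levels were 5.03, 5.32 and 6.35 in the sham arrays and 6.59, 8.28 and 5.79 in the DJB arrays. The sham mean of 5.57 lay under 6.11, the median of all rows, and the DJB mean of 6.89 above it, so the fold may be understated. The difference of 1.32 ± 0.56 (2.50-fold higher after DJB) did not pass over all genes (adjusted p = 0.335) or when adjusted over the list alone (adjusted p = 0.0620). An exact two-sided permutation test of the 3 DJB against the 3 sham values gave p = 0.2, where the smallest p this design allows is 0.1. The difference was 0.62 without DJB 2 and 1.87 without DJB 3.

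**Figure D2:**
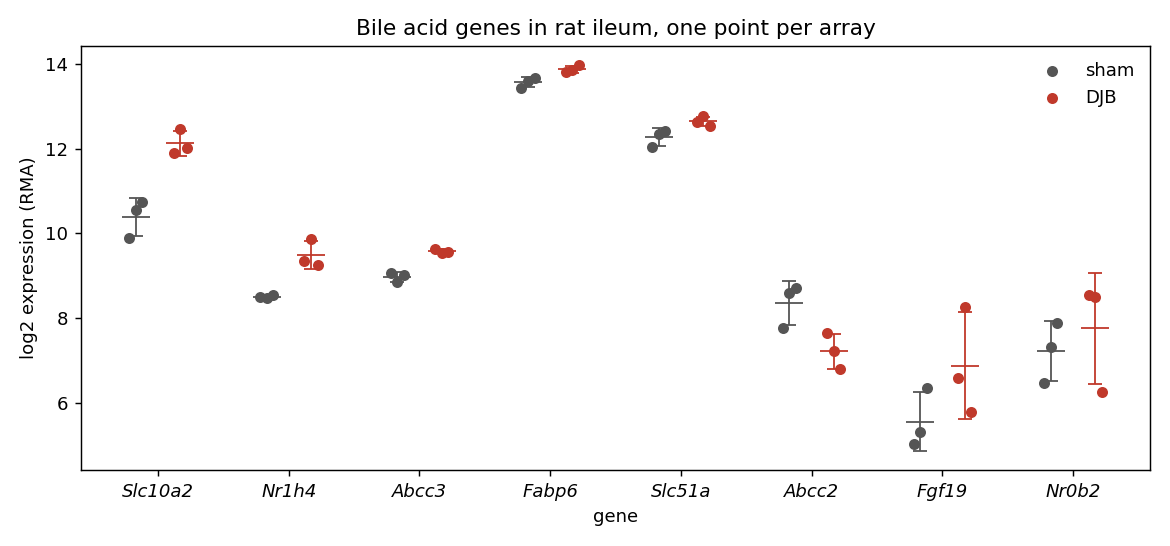
Log2 expression (RMA) of 8 bile acid genes in the ileum, 1 point per array, for 3 sham (grey) and 3 DJB (red) rats, with horizontal bars at the mean and error bars of 1 SD. Slc10a2, Nr1h4, Abcc3, Fabp6 and Slc51a separate the groups with DJB higher, and Abcc2 with DJB lower. In contrast, 1 DJB array (5.79) of Fgf19 lies among the sham arrays and 1 of Nr0b2 (6.26) lies below them.

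In the cholesterol synthesis and uptake list, all 19 measured members were higher after DJB, 13 rose over all genes and all 19 rose when adjusted over the list alone. Sqle changed by 1.74 ± 0.09 (adjusted p = 5.2e-05), the sterol methyl oxidase gene Msmo1 by 1.42 ± 0.09, the isomerase gene Idi1 of the mevalonate pathway by 1.40 ± 0.10, and Cyp51, the lanosterol demethylase, by 1.18 ± 0.10. The smallest change was that of Srebf2, which encodes the transcription factor driving the pathway, at 0.25 ± 0.10. The mean over the list was 0.81 ± 0.02 (SE, n = 3 per group), and camera called it higher (adjusted p = 1.51e-27). This was the only list of 35 whose camera call held with an estimated correlation (adjusted p = 0.00911), and the only one called by fry (adjusted p = 5.03e-05). Leaving out any 1 array kept the list called and left 17 or 18 members past the list-alone threshold.

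The sterol transport and LXR target list moved the other way, with all 11 measured members lower. Abcg5 (-2.0 ± 0.32), Abcg8 (-1.72 ± 0.24) and Scarb1, a lipoprotein receptor (-0.90 ± 0.11), fell over all genes, and 8 fell when adjusted over the list alone, among them the phospholipid-remodelling enzyme gene Lpcat3 at -0.44 ± 0.11. Camera called the list lower (mean -0.67 ± 0.17, adjusted p = 1.47e-11), which was not kept with an estimated correlation (adjusted p = 0.559). The calls of Abcg5 and Abcg8 ended without sham 2, sham 3, DJB 2 or DJB 3 (adjusted p up to 0.142 and 0.0941), that of Scarb1 without sham 3 (adjusted p = 0.0545), and 4 members passed over the list alone without sham 3.

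**Figure D3:**
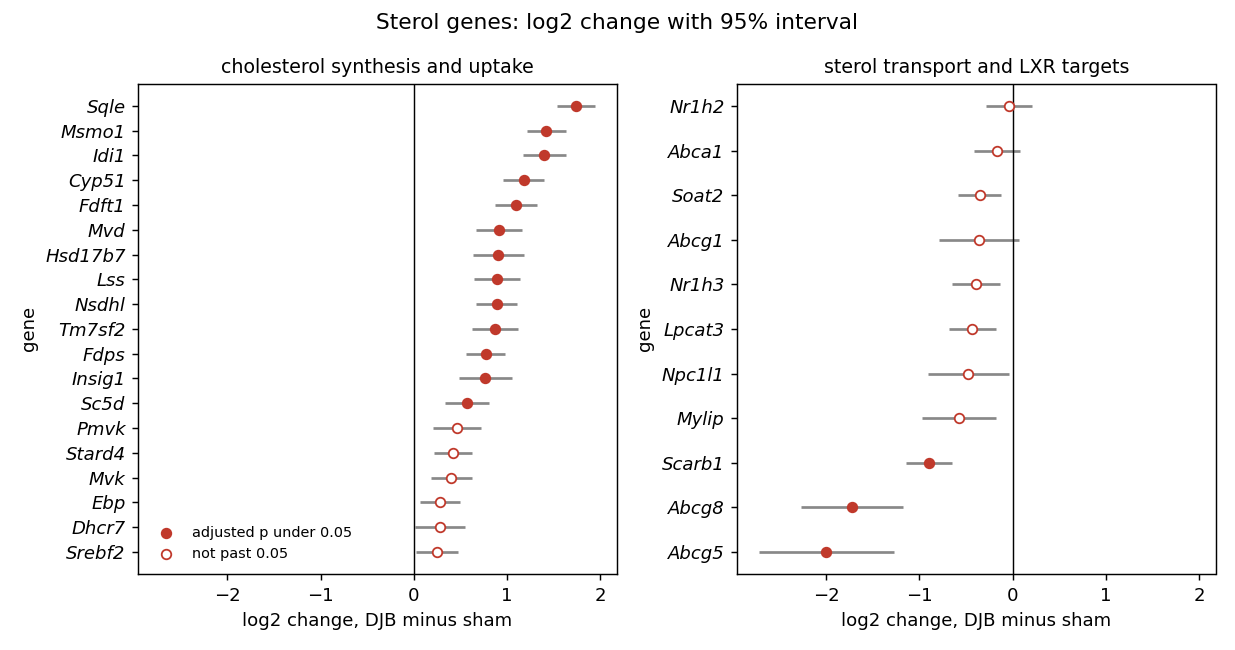
Log2 change after DJB (DJB minus sham, 3 arrays each) of the cholesterol synthesis and uptake genes (left) and of the sterol transport and LXR target genes (right), with 95% intervals as lines and filled points for genes with an adjusted p under 0.05 over all genes. The 19 genes on the left lie above 0, from 0.25 to 1.74, and the 11 on the right below 0, down to -2.0.

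Fat absorption and chylomicron genes were lower in 17 of 20 measured members. Apoc3, an apolipoprotein of chylomicrons, fell by 1.49 ± 0.19 and the fatty acid receptor gene Cd36 fell by 0.98 ± 0.15 over all genes, and 8 members fell when adjusted over the list alone, including Apoa4 (-0.91 ± 0.17) and the triglyceride synthesis gene Dgat1 (-0.36 ± 0.10). Camera called the list lower (mean -0.34 ± 0.12, adjusted p = 1.82e-10), and with an estimated correlation it did not pass (adjusted p = 0.559). Apoc3 lost its call without sham 2, sham 3 or DJB 2 (adjusted p up to 0.0605) and Cd36 without any 1 of the sham arrays or DJB 2 (up to 0.119), and the list-alone count was 3 without sham 2, sham 3 or DJB 2 and 4 without DJB 3.

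Brush border genes of digestion and nutrient transport were lower in 14 of 19 members. Treh, which splits trehalose, fell by 1.45 ± 0.26 and the peptidase gene Ace fell by 0.98 ± 0.16 over all genes, and 6 fell when adjusted over the list alone, among them the sugar transporter genes Slc2a2 (-1.02 ± 0.22) and Slc2a5 (-0.65 ± 0.16). Sucrase-isomaltase, Si, at -0.09 ± 0.10, aminopeptidase N, Anpep, at 0.06 ± 0.10, and the microvillus gene Vil1 at -0.01 ± 0.10 did not pass, and the sign of Anpep turned after another quantile normalisation. The list was called lower by camera (mean -0.32 ± 0.10, adjusted p = 5.59e-05), with adjusted p = 0.559 with an estimated correlation. Treh was not called without any 1 of the sham arrays, DJB 2 or DJB 3 (adjusted p up to 0.159), nor Ace without any 1 of the sham arrays or DJB 2 (up to 0.149).

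Markers of the upper small intestine went both ways. Of 8 measured, the folate transporter gene Slc46a1 and the calcium-binding protein gene S100g (-1.10 ± 0.13, called whichever array was left out) fell over all genes. When adjusted over the list alone 4 fell, with the transcription factor gene Gata4 at -1.18 ± 0.23, and 2 iron transporter genes rose, Slc40a1 at 0.49 ± 0.09 and Slc11a2 at 0.43 ± 0.11 (4 rises without DJB 3). The list was not called (mean -0.70 ± 0.19, camera adjusted p = 0.0698), but camera called it lower without sham 1 or DJB 2 (adjusted p down to 0.0115). The gluconeogenesis list of 8 genes was called lower (mean -0.34 ± 0.17, adjusted p = 0.0146) but not with an estimated correlation (adjusted p = 0.639) or without sham 3 (adjusted p = 0.127). None of its members passed over all genes, and the glucose-6-phosphate transporter gene Slc37a4 (-0.57 ± 0.13) and the phosphatase gene G6pc1 (-1.30 ± 0.37) fell when adjusted over the list alone, while Pck1 (-0.82 ± 0.29) and Pck2 (0.17 ± 0.09) did not pass. The falls over the list alone were 0 without sham 3 and 1 without DJB 2.

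Xenobiotic metabolism genes were lower in 18 of 24 members, with 1 fall over all genes, that of the nuclear receptor gene Nr1i3 (-0.98 ± 0.18). When adjusted over the list alone 8 fell, such as the glutathione transferase genes Gsta3 (-0.99 ± 0.22) and Gsta4 (-0.59 ± 0.11), and 3 rose, among them the quinone reductase gene Nqo1 (0.56 ± 0.13). Camera called the list lower (mean -0.40 ± 0.21, adjusted p = 6.48e-05), and adjusted p = 0.639 with an estimated correlation. The call of Nr1i3 ended without any 1 of the sham arrays, DJB 2 or DJB 3 (adjusted p up to 0.174), the falls over the list alone were 4 without DJB 3, and the rises were 1 without sham 2 and 2 without sham 1 or any 1 of the DJB arrays.

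Cell cycle genes were higher in 24 of 25 members by small amounts. Ccnb1, the mitotic cyclin B1, rose by 0.60 ± 0.11 over all genes, and Mcm5, a part of the replicative helicase, joined it at 0.62 ± 0.12 when adjusted over the list alone, while Ccnb2 (0.32 ± 0.10) and Aurkb (0.33 ± 0.11) did not pass. The list was called higher by camera (mean 0.26 ± 0.10, adjusted p = 2.52e-06) and not with an estimated correlation (adjusted p = 0.639). Without DJB 2 the list-alone count of 2 was 13, and the call of Ccnb1 ended without any 1 of the 6 arrays (adjusted p up to 0.190).

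In the Paneth cell and antimicrobial list of 19, Reg3b and Reg3g rose over all genes, and when adjusted over the list alone Reg1a (0.73 ± 0.18) rose too while 2 fell, the defensin gene Defa6 (-0.68 ± 0.18) and Nupr1 (-0.35 ± 0.11). The falls were 0 without DJB 1 or DJB 3 and 1 without sham 1. That list was not called (mean 0.10 ± 0.12, adjusted p = 0.961), and its median of 0.03 turned negative when each array was centred on its median. Crypt stem cell genes (14, mean -0.05 ± 0.07, adjusted p = 0.181) held 1 fall over the list alone, the stem cell receptor gene Lgr5 at -0.63 ± 0.15, and 1 rise, Prom1 at 0.38 ± 0.10. The rise was lost without any 1 of the 6 arrays and the fall without sham 1, sham 3, DJB 2 or DJB 3, and camera called the list lower without sham 2 (adjusted p = 0.0309). Goblet cell genes (11, mean -0.04 ± 0.02, adjusted p = 0.189) had no member past either threshold, with Agr2 at -0.32 ± 0.11 and Spdef at -0.25 ± 0.10. Enteroendocrine genes (21, mean 0.06 ± 0.13, adjusted p = 0.896) had none either, with the upper-gut hormone genes Gip at -0.49 ± 0.14 and Cck at -0.33 ± 0.11, though 1 fell over the list alone without sham 3. The tuft cell list of 9 was called lower (mean -0.16 ± 0.15, adjusted p = 0.0444), but adjusted p = 0.671 with an estimated correlation. No tuft cell gene passed, with Alox5ap at -0.29 ± 0.12, but 4 fell over the list alone without sham 2, and the call ended without sham 1, sham 3, DJB 2 or DJB 3 (adjusted p up to 0.253).

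Among immune cell lists, B cell and plasma cell genes were called lower (15 genes, mean -0.24 ± 0.27, camera adjusted p = 0.00888), which did not hold with an estimated correlation (adjusted p = 0.671). The transcription factor gene Spib (-0.83 ± 0.17) fell when adjusted over the list alone, and Cr2 (-1.08 ± 0.66) and Ms4a1 (-0.73 ± 0.51) differed by less than the SD of the DJB arrays. Macrophage, dendritic cell and neutrophil genes were called higher (19 genes, mean 0.19 ± 0.07, adjusted p = 0.0132), and adjusted p = 0.639 with an estimated correlation. The lipopolysaccharide co-receptor gene Cd14 (0.54 ± 0.12) rose when adjusted over the list alone, with Cd163 at 0.45 ± 0.14 and Csf1r at 0.35 ± 0.11 not past it. Over the list alone the Spib fall was lost without sham 1, DJB 2 or DJB 3. The 1 rise in the macrophage list was 0 without sham 1, sham 2, DJB 1 or DJB 3 and 6 without DJB 2. The B cell call ended without sham 2 or DJB 2 (adjusted p up to 0.266) and the macrophage call without sham 3 or DJB 3 (up to 0.262). T and NK cell genes were not called (22, mean 0.24 ± 0.21, adjusted p = 0.0708), with the granzyme gene Gzmb at 1.21 ± 0.43 and Cd3d at 0.49 ± 0.18, and 5 rose over the list alone without DJB 2. Camera called that list higher without sham 2, DJB 1 or DJB 2 (adjusted p down to 3.3e-05). Mast cell and eosinophil genes were not called (17, mean -0.02 ± 0.07, adjusted p = 0.246), with the protease genes Mcpt1 at -0.53 ± 0.15 and Cpa3 at -0.36 ± 0.12. Of that list, 1 fell over the list alone without sham 3, and 1 fell and 1 rose without DJB 2. MHC class II genes were not called (11, adjusted p = 0.944), and their mean of 0.03 ± 0.08 and median of 0.01 lay above 0 while the camera statistic lay below, the median turning negative with another quantile normalisation or centring. RT1-Da stood at 0.31 ± 0.09 and Ctss at 0.27 ± 0.12.

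Inflammatory cytokine and NF-kappaB target genes were not called (20, mean 0.24 ± 0.01, adjusted p = 0.125). The chemokine gene Ccl20 (0.99 ± 0.26) and the inhibitor gene Nfkbia (0.34 ± 0.09) rose and Il18 (-0.48 ± 0.13) fell when adjusted over the list alone. Without sham 2 or sham 3 the list had 0 rises and 0 falls. It had 1 rise and 0 falls without sham 1, DJB 2 or DJB 3, and 3 rises without DJB 1. Camera called it higher without DJB 3 (adjusted p = 0.0277). Interferon response genes were not called (31, mean 0.13 ± 0.16, adjusted p = 0.249), with Ifi27 at 0.75 ± 0.18 and Ifi47 at 0.49 ± 0.19, and 1 rose and 1 fell over the list alone without DJB 1 and 4 rose without DJB 2. Without DJB 2 camera called the list higher (adjusted p = 0.00700).

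Of the lists for the gut wall below the epithelium, fibroblast and extracellular matrix genes were called higher (18 genes, mean 0.26 ± 0.16, adjusted p = 0.0130), but adjusted p = 0.765 with an estimated correlation. When adjusted over the list alone 6 rose, among them the collagen genes Col1a1 (0.71 ± 0.21), Col3a1 (0.52 ± 0.16) and Col1a2 (0.52 ± 0.16) and the fibrillin gene Fbn1 (0.55 ± 0.16). That count was 0 without sham 2, sham 3, DJB 1 or DJB 2 and 10 without DJB 3, and the call of the list ended without sham 2, DJB 1 or DJB 2 (adjusted p up to 0.110). Smooth muscle genes (17, mean 0.18 ± 0.18, adjusted p = 0.211; Pcp4 at 0.60 ± 0.18, Acta2 at 0.25 ± 0.10), enteric neuron and glia genes (16, mean -0.06 ± 0.11, adjusted p = 0.0708; Stmn2 at -0.44 ± 0.16, Prph at -0.21 ± 0.13) and endothelial genes (12, mean -0.03 ± 0.14, adjusted p = 0.292; Prox1 at -0.39 ± 0.14, Lyve1 at 0.19 ± 0.14) were not called. With 1 array left out camera called some of them: smooth muscle higher without sham 1 or DJB 3 (adjusted p down to 0.00143), neurons and glia lower without sham 2, DJB 1 or DJB 2 (down to 0.00912) and endothelium lower without DJB 1 (0.0319). Over the list alone 2 smooth muscle genes rose without DJB 3.

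Tissues next to or passing through the ileum gave no called list with all 6 arrays. Without sham 2 camera called exocrine pancreas higher and red blood cells lower (adjusted p = 0.0495 for both). Adipocyte genes (10, adjusted p = 0.516) had a mean of -0.02 ± 0.17 and a median of 0.12, which differ in sign, with Pparg at -0.59 ± 0.17 and Cidec at -0.62 ± 0.25. Over the list alone 2 adipocyte genes fell without sham 1 and 1 rose without DJB 3. Exocrine pancreas genes were not called (12, mean 0.10 ± 0.10, adjusted p = 0.318), with Ctrl at 0.25 ± 0.12 and Ctrb1 at 0.18 ± 0.11. Red blood cell genes were not called (7, adjusted p = 0.0708), and their mean of 0.02 ± 0.07 had another sign than their median of -0.22 and the camera statistic. When adjusted over that list alone the carbonic anhydrase gene Car1 rose (2.58 ± 0.51, adjusted p = 0.0658 over all genes) while the globin genes Hbb-b1 (-1.09 ± 0.27) and Hbb (-1.0 ± 0.27) fell, with 3 falls without sham 3 and 1 without DJB 2.

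In fatty acid synthesis (14, mean 0.14 ± 0.08, adjusted p = 0.211), the elongase gene Elovl6 rose by 0.68 ± 0.12 over all genes, and when adjusted over the list alone 4 rose, among them the desaturase gene Fads2 (0.33 ± 0.10) and Acacb (0.32 ± 0.11), while malic enzyme, Me1, fell (-0.29 ± 0.10). In fatty acid oxidation (19, mean 0.09 ± 0.12, adjusted p = 0.246), 3 rose when adjusted over the list alone, including the carnitine palmitoyltransferase genes Cpt2 (0.54 ± 0.11) and Cpt1a (0.47 ± 0.10). That count was 0 without sham 1 and 2 without DJB 1 or DJB 2, and 1 gene fell without sham 2 or DJB 3. In glycolysis and hypoxia (20, mean 0.09 ± 0.03, adjusted p = 0.776), hexokinase 2, Hk2, rose by 0.84 ± 0.13 over all genes, and Pdk1 (-0.29 ± 0.10), Pfkp (0.25 ± 0.12) and Slc2a1 (0.18 ± 0.09) did not pass. Oxidative phosphorylation genes were not called (21, mean 0.04 ± 0.07, adjusted p = 0.944), with Cox5a at 0.39 ± 0.10 and Cox5b at -0.29 ± 0.13. The call of Hk2 ended without any 1 of the sham arrays or DJB 2 (adjusted p up to 0.124) and that of Elovl6 without any 1 array other than DJB 2 (up to 0.161), and the 4 list-alone rises in fatty acid synthesis were 1 whichever array was left out. The fall of Me1 over that list was lost in each of these 6 fits.

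Circadian clock genes were lower in 12 of 15 members, and camera called the list (mean -0.19 ± 0.09, adjusted p = 3.33e-04) but not with an estimated correlation (adjusted p = 0.559). Dbp, a transcription factor gene driven directly by the clock, fell by 0.94 ± 0.14 over all genes, a call that ended without any 1 of the sham arrays or DJB 3 (adjusted p up to 0.0985). Bhlhe41 (-0.30 ± 0.09), Tef (-0.37 ± 0.12) and Per3 (-0.59 ± 0.22) did not pass. Over the list alone 3 clock genes fell without sham 2, where 1 did with all arrays. Among signs of tissue handling, immediate early and heat shock genes (15, mean 0.13 ± 0.22, adjusted p = 0.310; Nr4a1 at 0.65 ± 0.23, Ier3 at 0.40 ± 0.15) and unfolded protein and integrated stress response genes (19, mean 0.09 ± 0.06, adjusted p = 0.816; Ddit3 at -0.35 ± 0.10, Sdf2l1 at 0.56 ± 0.17) were not called, though without DJB 3 camera called the former higher (adjusted p = 9.12e-04) and 5 of them rose over the list alone. In the unfolded protein list 1 rose and 1 fell over the list alone without DJB 1, and 1 rose without DJB 2.

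**Figure D4:**
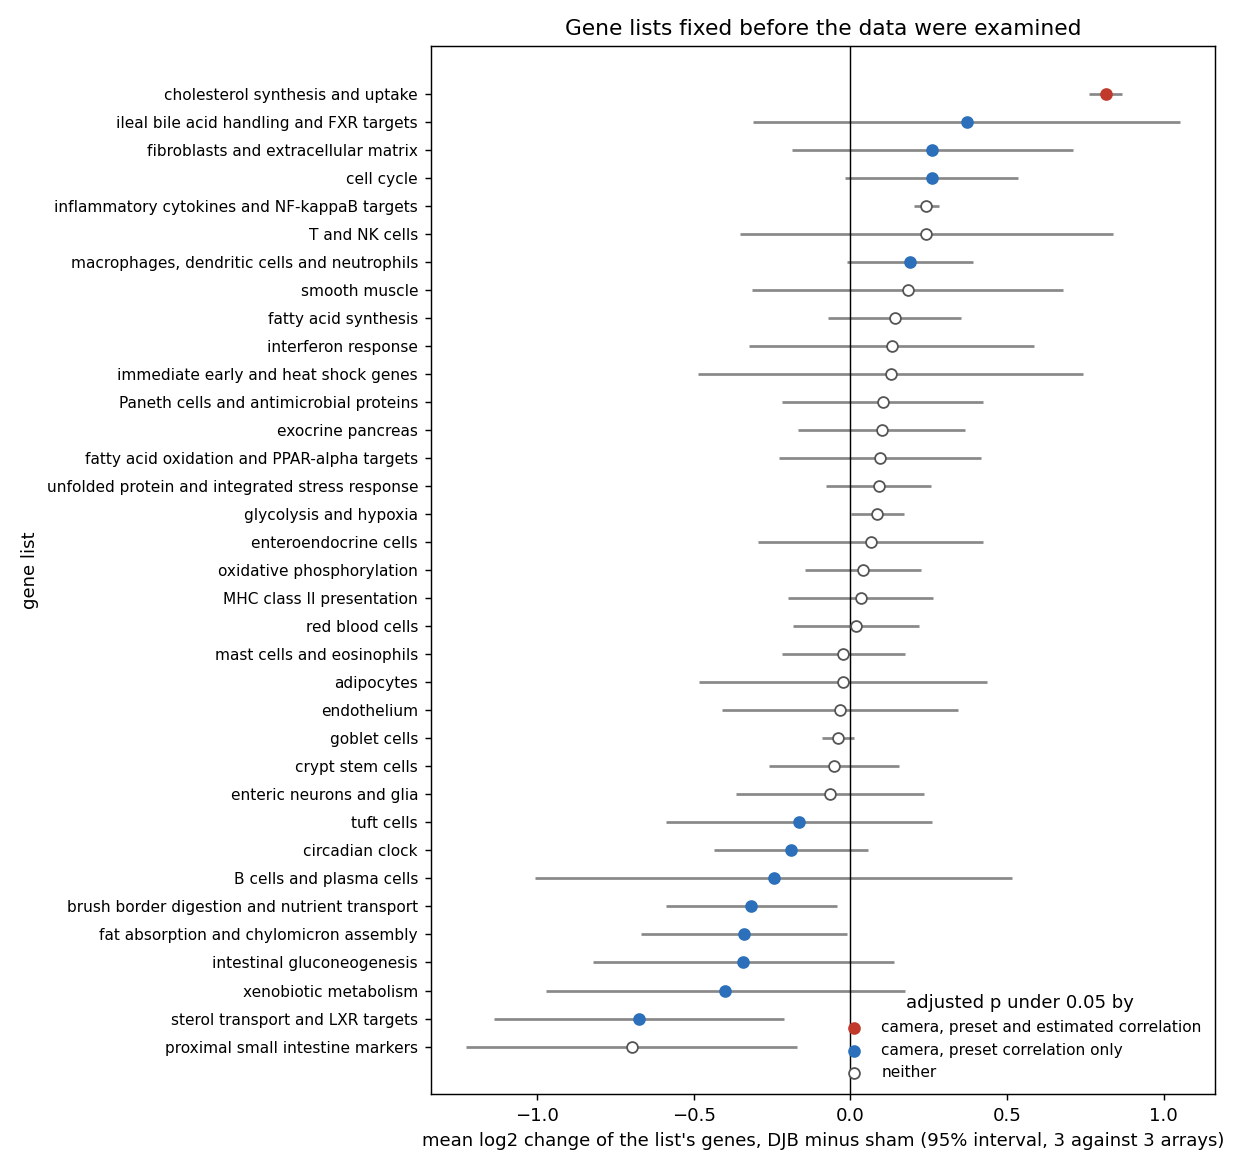
Mean log2 change after DJB (DJB minus sham, 3 arrays per group) of the genes of each of the 35 lists, with 95% intervals of the difference between the groups as lines. Red marks the list called by camera with both the preset and an estimated correlation (cholesterol synthesis and uptake, mean 0.81), blue those called with the preset correlation only, and open points those called with neither.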

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

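The tests of other array splits and of dividing cells were chosen after the results they concern were seen. Single outlying arrays were not tested for in groups of 3, and the design has 1 comparison, so that no difference between comparisons could be tested. Outside the main measurement, among the 13581 array rows without a gene name, 17 were higher and 30 lower after DJB at a limma adjusted p under 0.05 over all rows, and 1465 had an unadjusted p under 0.05. The largest rise was that of row 10797161, from 5.64 to 8.39 (log2 change 2.75 ± 0.41, SE), and row 10767320 changed by -4.18 ± 0.56, from 11.19 to 7.02. The 30 lower rows hold 20 distinct sets of values (10 rows share 1 set on all 6 arrays) and are not 30 separate transcripts. Which genes these rows measure was not analysed here.

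A pattern to weigh is that Abcg5, Abcg8, Apoc3, Cd36, Treh and Ace fell while Slc10a2 and Nr1h4 rose. Fewer mature enterocytes in the DJB pieces are argued against only as a loss as large as the falls. Genes common to enterocytes changed by a mean of -0.10 (95% interval -0.28 to 0.08), against a median of -1.05 for the genes called lower. That median comes from genes selected for falling, and a smaller loss, down to -0.28, is not excluded. Of the 12 enterocyte genes, Slc9a3 stood at -1.0 ± 0.43. Some, such as Si at 12.95 in sham, lay at high levels, where a difference can be understated. The position of the pieces along the gut stays open. Distal minus proximal gut hormone genes differed by -0.025 between the groups (95% interval -0.55 to 0.50), too wide to exclude pieces taken further down. The 10 posterior Hox genes measured were all slightly higher (mean 0.15, 95% interval -0.07 to 0.36). Most of them lay under the limit for dim rows, a log2 level of 6.11, and the median change of all genes was 0.05. Of 8 upper-intestine markers 4 were higher and 4 lower. The falls were larger, and the mean was -0.70 (95% interval -1.23 to -0.17). A response to the rerouted food and bile, which the design would also produce, cannot be told apart from sampling position here.

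A related pattern is the rise of cholesterol synthesis genes beside the fall of Abcg5 and Abcg8. The cholesterol list exceeded the cell cycle list by 0.55 (95% interval 0.32 to 0.79), a comparison chosen after both list means were seen. If more dividing cells raised their own genes most, a larger share of them alone would not account for the cholesterol rise. That premise was not tested. A lower sterol content of the cells may be a candidate explanation. It would lower LXR targets outside the apical transporters as well. These changed by -0.39 (5 of 5 lower, 95% interval -0.77 to 0.00050, exact permutation p = 0.1, the smallest possible), which leaves that explanation open. The 5 genes also belong to the sterol transport and LXR target list, in which all 11 members were lower, and are not a separate check of it.

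The lower clock genes form the last pattern. Tissue taken at another time of day in the groups could produce it. Evening genes (Dbp, Tef, Per1, Per2, Per3, Nr1d1 and Nr1d2) were lower in 7 of 7 (mean -0.42, 95% interval -0.73 to -0.10). The 5 morning genes measured had a mean of 0.10 (95% interval -0.36 to 0.56), with 3 higher and 2 lower. Among them Bmal1 moved most, at 0.59 ± 0.24 (limma adjusted p = 0.316). Evening minus morning genes differed by -0.51 between the groups (95% interval -1.09 to 0.06, exact permutation p = 0.1, the smallest possible), so time of day and surgery cannot be told apart, and the labels give no hour.

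The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes sham and DJB arrays on each side. A difference between the groups then adds to the spread within a side, which can lower the number of genes called. The counts below therefore do not show what chance alone would give. For the number of genes called, 1 of the 10 splits, the real one, reached 112, and the highest other split called 0. For genes at an unadjusted p under 0.01 and 1.5-fold, 1 of the 10 reached 200, and the highest other split had 29. For lists called by camera with the preset correlation, 6 of the 10 splits, the real one included, reached 13, and the highest other split called 17. With an estimated correlation the real split called 1 list and the other splits 0. The absolute mean change of the cholesterol list was 0.815 in the real split and at most 0.297 in the others. Mixing the groups shrinks any difference between them in this way, so these values do not bear on chance.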

How the results depend on the processing

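All alternatives were planned, and the cause of the shifts was not tested beyond the fewer genes or arrays that an alternative itself leaves. The number of genes changed was 112, and it was 225 without dim rows (108 shared with the 112), 313 with an intensity trend and robust prior (101 shared), 173 with array weights (112 shared) and 2 with a plain two-sample test, and it ranged from 33 (without sham 3) to 108 (without DJB 1) with 1 array left out. Repeated quantile normalisation gave 119 (105 shared), centring 126 (103 shared) and the mean of all rows of a gene 113 (112 shared). Tested singly over all rows, 100 rows passed, 47 of them without a gene name, and 51 of the 112 genes were among them. The 57 higher and 55 lower genes were 51 and 68 after quantile normalisation, 53 and 73 after centring, 189 and 124 with the trend, 38 and 70 without DJB 1 and 23 and 10 without sham 3, so the near-even split holds for some settings only. The array weight was 0.553 for DJB 1 and at least 0.861 for each other array. Of the 112 genes, 4 lay under the limit for dim rows, a log2 level of 6.11. The replicate block, with same-numbered sham and DJB arrays paired, gave 50 genes (47 shared), and 27 of the 47 called genes named kept their call with it. The labels do not say whether the numbers pair the rats. The deviations of same-numbered arrays correlated at 0.0053, -0.121 and -0.149, and those of differently numbered sham and DJB arrays at -0.0570 to 0.170. These values give no sign of pairing but cannot exclude it. The count at an unadjusted p under 0.01 and 1.5-fold was 200, 396 over all rows, which are more than the genes, 95 in the plain test, and 182 to 233 with 1 array left out. The Fgf19 difference stayed between 0.62 and 1.87 and passed in none of these alternatives (adjusted p 0.180 to 0.586). Lists called were 13, 9 without dim rows, 17 with the block and 10 to 16 with 1 array left out, but 1 with an estimated correlation and 1 with fry, the cholesterol list in both. The lists were not recomputed over all rows or with the plain test. No called gene named or called list changed its sign under these alternatives.

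Signs turned only for values near 0 that were not called, and the cause was not tested. With array weights the log2 change of Slc6a19 was 0.076, Vil1 was 0.0025, Olfm4 0.0014, the goblet median 0.0082 and the MHC class II median -0.022. After another quantile normalisation Anpep was -0.017 and the MHC class II median -0.019, and after centring the MHC class II median was -0.024 and the Paneth median -0.0027. Without dim rows the medians were -0.25 for Paneth, 0.0036 for endothelium and -0.071 for adipocytes. With 1 array left out, the log2 change of Vil1 ranged from -0.0559 to 0.0252, that of Gcg from -0.051 to 0.16, that of Pyy from -0.31 to 0.21 and that of Olfm4 from -0.063 to 0.0045. The log2 change of Slc3a1 spanned -0.0825 to 0.14 and the log2 change of Slc6a19 -0.15 to 0.11. For list medians the ranges spanning 0 were -0.0090 to 0.18 for fatty acid oxidation, -0.0068 to 0.22 for enteroendocrine, -0.082 to 0.022 for goblet, -0.0051 to 0.14 for Paneth, -0.064 to 0.0035 for crypt stem, -0.069 to 0.036 for mast cell, -0.064 to 0.091 for MHC class II, -0.17 to 0.00046 for neuron and glia, -0.15 to 0.12 for endothelial, -0.0091 to 0.13 for unfolded protein and -0.027 to 0.082 for oxidative phosphorylation genes.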

Other observations

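All genes in this part except Suox and Car1 were chosen after their values were seen, and each value is a limma log2 change ± SE, DJB minus sham, from 3 arrays per group. No list of carbonic anhydrases, which interconvert carbon dioxide and bicarbonate, was fixed or tested. Of 4 such genes, Car4 rose by 1.11 ± 0.17 and Car12 by 0.96 ± 0.17, both membrane-bound forms, while the cytosolic Car2 fell by 1.69 ± 0.24. Car1 was 2.58 ± 0.51 higher without passing over all genes (adjusted p = 0.0658). The calls of Car4 and Car12 ended without any 1 of the sham arrays, DJB 2 or DJB 3 (adjusted p up to 0.105 and 0.139), and that of Car2 without sham 2 or sham 3 (up to 0.0924). The claudin gene Cldn2, which encodes a cation pore of tight junctions, rose by 1.07 ± 0.10, whichever array was left out.

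No list of nucleoside or amino acid transporters was fixed or tested. The nucleoside transporter gene Slc28a1 was lower at -1.56 ± 0.27, as were the amino acid transporter genes Slc36a1 at -1.26 ± 0.19 and Slc7a8 at -1.10 ± 0.20. Of other amino acid transporter genes, Slc7a9 (0.20 ± 0.10), Slc3a1 (0.06 ± 0.15) and Slc6a19 (-0.04 ± 0.16) did not pass. Also lower were the purine and pyrimidine enzyme genes Ada, at -1.34 ± 0.21, and Upp1, at -1.22 ± 0.21. The sulfate transporter gene Slc13a1 rose by 0.86 ± 0.15 beside sulfite oxidase, Suox (1.74 ± 0.22). Apart from Suox, whose repeats are given above, these calls changed with the arrays: Slc13a1 was not called without any 1 of the 6 arrays (adjusted p up to 0.130), and the others each lost the call without 4 or 5 of the arrays in turn (up to 0.173 for Slc28a1, 0.101 for Slc36a1, 0.167 for Slc7a8, 0.105 for Ada and 0.141 for Upp1). Outside the fixed cholesterol list, Acat2, which makes the acetoacetyl-CoA that feeds the pathway, rose by 1.04 ± 0.11, and the sterol-regulated gene Tmem97 by 0.79 ± 0.13, the latter called only with all 6 arrays (adjusted p up to 0.111 without 1). Hormone genes of the lower gut stayed near 0 without passing, with Gcg at 0.05 ± 0.14 and Pyy at -0.06 ± 0.24, and the crypt gene Olfm4 stood at -0.02 ± 0.09.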
